A study of Mus musculus with 20 samples.

How the data were processed

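Genomic DNA from the tails of 10 C57BL/6 mice of 1 family was measured by array comparative genomic hybridization, in which the DNA of a studied mouse and that of a reference mouse carry different dyes (Cy5, read as red, and Cy3, read as green) and compete for the same probes. All mice were hybridised against 1 reference male of the same colony. Each mouse was run on 2 arrays with the dyes exchanged, giving 20 arrays. Per the labels, the mice are the father, the mother and 8 F1 offspring. The 2 arrays of a mouse hold the same DNA and were averaged into 1 replicate.

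The deposited scanner files come from Agilent Feature Extraction 10.7.1.1, per the file headers, with coordinates on mouse build mm9. The signal intensity values were background-subtracted, spatially detrended and scaled by 1 linear dye factor per channel by the authors' run of this program, per the file headers, with no lowess step. The deposited log10 ratio of red over green equals the ratio of the processed signals to within 0.001 at 99.992% or more of the spots on every array. A second deposited table holds log2 ratios; set against the scanner values, its direction is reference over mouse on every array, with slopes per unit of log10 ratio of 3.284 to 3.322 where the mouse was in Cy3 and of -3.322 to -3.268 where it was in Cy5. Its column medians lie between -0.0097 and 0.0176, and what further adjustment it had is not given in the sources used here. It served as an alternative, turned to mouse over reference. The table has 0 per-sample columns that were left unused.

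Each array has 966371 probe spots. The 6745 control spots were left out, as were the 135 to 518 spots per array marked as non-uniform or population outliers; 0 spots were saturated. Between 97.592% and 99.666% of the spots were well above background in both channels. The log2 ratio of mouse over reference was taken from the processed signals, with the direction from the dyes in the labels, and each array was centred on the median of its autosomal probes, without loess or quantile normalization. Spots of 1 probe were averaged, giving 950749 probes, of which 950622 are autosomal, 68 lie on X, 23 on Y and 36 on unplaced contigs. The median distance between the starts of neighbouring autosomal probes was 2053 bp. The number of arrays limits the precision of the values. Within 1 dye orientation, arrays of different mice correlated across probes with r from -0.08 to 0.59.

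The noise of a mouse is the derivative spread, the standard deviation of the differences between neighbouring probes divided by the square root of 2. The single-probe screen counted autosomal probes with a log2 ratio of at least 0.5 in size and the same turned direction in both orientations; the background is the number past the same size with opposite directions, which follow the dye and not the mouse. Regions were called by an interval scan on the autosomes: values were divided by the derivative spread of the mouse and limited to 6 in size, and intervals of at least 3 probes (up to 2000) with a score, the sum over the square root of the number of probes, of at least 6 in size were enumerated and taken from the highest score down without overlap, in place of the planned recursive search. The mean had to reach 0.25 in size, and 0.2 in each orientation in the same direction. The score is not a p-value. The background is the same scan on 0.5 of the difference between the turned orientations, on 5 random orders of the probes drawn for each mouse separately, and on 20 random orders that all mice share, which keep the correlation between mice. Calls of 1 direction that overlap by at least 1 probe were merged across mice. For regions called in exactly 1 parent, the number of F1 carriers among 8 was tested against 0.5 with an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 13 such regions.

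Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05): the 8 F1 mice against 0, and the 8 F1 mice against the 2 parents. The first test leaves out the reference mouse's own spread. Chromosome means of the 8 F1 mice were tested against 0 with an exact two-sided sign-flip permutation test, adjusted over the 19 autosomes. X and Y probes were kept out of these tests and of the called regions. Their means served later only as levels with which autosomal segments were compared. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

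The scan was tested on simulated data, with segments placed in the permuted values of each mouse. Over the 950622 probes of all 10 mice it found 59.0% of losses of -0.6 and 33.2% of gains of 0.5 with 3 probes, 80.8% and 68.8% with 5 probes, 97.6% and 89.8% with 10 probes, and 100.0% of both with 30 probes. In the mother, the noisiest mouse, it found 84.0% of losses and 26.0% of gains with 10 probes, and 2.0% and 0.0% with 3 probes. On simulated values for 950622 probes, limma for F1 against the reference found 11.9% of probes shifted by 0.25, 79.1% of those shifted by 0.5 and 100% of those shifted by 1. For F1 against the parents it found 0%, 4.5% and 65.2%. These values were drawn independently for every mouse with the spread of the F1 mice. The mother's larger noise and the correlation between mice were left out, so the rates in the data may differ.

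The main tests, thresholds and the alternatives that follow were fixed before the data were examined. These were score thresholds of 5 and 8, at least 2 and at least 5 probes, means of 0.15 and 0.4, each mouse against the median of the others, normexp background correction (offset 50) on the median signals (mean signals are not among the columns used), loess within each array, the authors' table, a running median over 2001 probes, each orientation alone, and a filter on dim probes. Further alternatives were other screen levels (0.35 and 0.75), another merging rule, a looser rule for carriers, each mouse left out of the limma fits in turn, and the scan batch as a random block or within batches. Chosen after the data were seen were the 20 probe orders shared by all mice, the runs without the mother and F1 replicates 3 and 5, without F1 replicates 1, 3 and 4 or without the calls of F1 replicate 5, the score of 8 for the classes by family member, the alternatives for regions in 2 or more mice, and those for the sex chromosome and region means. The scanner headers place the arrays in 6 scan batches. Batch 1 holds the father and the mother, batch 2 holds F1 replicates 1 and 2, batch 3 holds 3 and 4, batch 4 holds 5 and 7, batch 5 holds 8 and batch 6 holds 6.

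Regions named in the text follow a rule fixed beforehand. They are every region called in at least 2 mice (at most 15, by number of mice and then mean), the 20 highest-scoring regions called in F1 mice and in neither parent, and the 5 highest-scoring regions per parent called in that parent only. The scanner files give coordinates and no gene names, and the gene table used here (assembly GRCm38) is of another build, so no gene was named from coordinates. The planned gene lists and the GC trend were not analysed here for that reason. The secondary arrays and copy number assays named in the study's design text, and other families, were also not analysed here.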

Results

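Copy number along the autosomes was measured in the tail DNA of 1 mouse family on arrays of 950749 probes, each mouse against the same reference male. The family has 1 father, 1 mother and 8 F1 offspring, and each of the 10 mice was measured on 2 arrays with exchanged dyes (20 arrays). Per the series title, a male was exposed to gamma rays at 0.05 mGy per day for 400 days, a product of 20 mGy. The design text describes the male of this family as not irradiated, so the father's exposure is stated in both ways. No other family was analysed here, so the values describe this family and give no effect of dose. The father and the mother each have 1 sample, so values of single mice have no replicate other than the dye exchange. Errors given for a region are standard errors over its probes.

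Median background-subtracted signals per array ran from 57.5 to 165.2 in green and from 77.2 to 150.7 in red. The derivative spread of the averaged log2 ratio was 0.17 ± 0.04 (SD, n = 8) in the F1 mice, from 0.13 in F1 replicate 8 to 0.25 in F1 replicate 3. It was 0.15 in the father and 0.29 in the mother. The turned values of the 2 orientations of a mouse correlated with r between -0.44 and -0.17 in 8 mice, and with r of 0.17 in the mother and 0.16 in F1 replicate 3, across probes, which are not independent replicates.

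The sex chromosome probes show the size of a known copy difference. Against the male reference, the mother had a mean log2 ratio of 0.79 ± 0.03 (SE over 68 probes) on X and -1.51 ± 0.18 (SE over 23 probes) on Y. On X, F1 replicate 7 had 0.87 and F1 replicate 8 had 0.88, and the other 6 F1 mice and the father lay between -0.03 and 0.02. On Y, F1 replicate 7 had -1.55 and F1 replicate 8 had -1.52, and the other 6 F1 mice and the father lay between -0.02 and 0.10. With normexp background correction the mother's X mean was 0.45 and the Y mean -0.55.

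The first comparison asks which copy number differences of the F1 mice are also seen in a parent. A segment of chromosome 4 (mm9, 101107131 to 101270535, 163 kb, 75 probes) was higher than the reference in all 10 mice. The father had a mean log2 ratio of 0.88 ± 0.02 and the mother 0.51 ± 0.03. F1 replicates 5, 6 and 7 had 0.89 ± 0.04, 0.93 ± 0.02 and 0.92 ± 0.02. F1 replicates 1, 2, 3, 4 and 8 had 0.54 ± 0.03, 0.54 ± 0.02, 0.53 ± 0.03, 0.51 ± 0.02 and 0.53 ± 0.02. Both orientations gave this gain in every mouse, with at most 0.13 between the orientation means over a call. Against the median of the other 9 mice, which removes what most mice share, the gain was called in 4 mice (the father and F1 replicates 5, 6 and 7), and in all 10 under the other scan alternatives. A difference that all mice share against 1 reference can lie in the reference mouse.

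A segment of chromosome 12 (56184969 to 56256271, 71.3 kb, 35 probes) was lower than the reference in the mother and in 4 of the 8 F1 mice. The mother had -0.64 ± 0.06, F1 replicate 3 had -0.65 ± 0.05, F1 replicate 4 had -0.63 ± 0.04, F1 replicate 5 had -0.65 ± 0.04 and F1 replicate 8 had -0.59 ± 0.04. The father and F1 replicates 1, 2, 6 and 7 lay between -0.03 and 0.00. Of the litter, 4 of 8 were carriers (exact two-sided binomial test against 0.5, p = 1.0, adjusted p = 1.0). With 8 mice this test can fall under 0.05 only for 0 or 8 carriers, since 1 carrier gives p = 0.0703, so it says little for any region with 1 to 7. This region was called in the same number of mice, 5, under every scan alternative run.

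A segment of chromosome 8 and one of chromosome 3 were called in the mother and in F1 replicates 7 and 8, the 3 mice with raised X and lowered Y values. On chromosome 8 (102125282 to 102254870, 130 kb, 47 probes) they had 0.26 ± 0.05, 0.24 ± 0.03 and 0.29 ± 0.02, against -0.05 to 0.04 in the other 7 mice. On chromosome 3 (25417435 to 25444229, 26.8 kb, 4 probes) they had -1.45 ± 0.22, -1.54 ± 0.25 and -1.56 ± 0.25, against -0.03 to 0.09 in the others. For both, 2 of 8 F1 mice were carriers (exact two-sided binomial p = 0.289, adjusted p = 0.313, a count that cannot pass with 8 mice). The chromosome 8 gain was called in 0 mice when the mean had to reach 0.4, in 1 mouse from the orientation with the mouse in Cy5 alone, in 2 from the other orientation alone, and in 2 mice with normexp or against the median of the other mice.

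**Figure D1:**
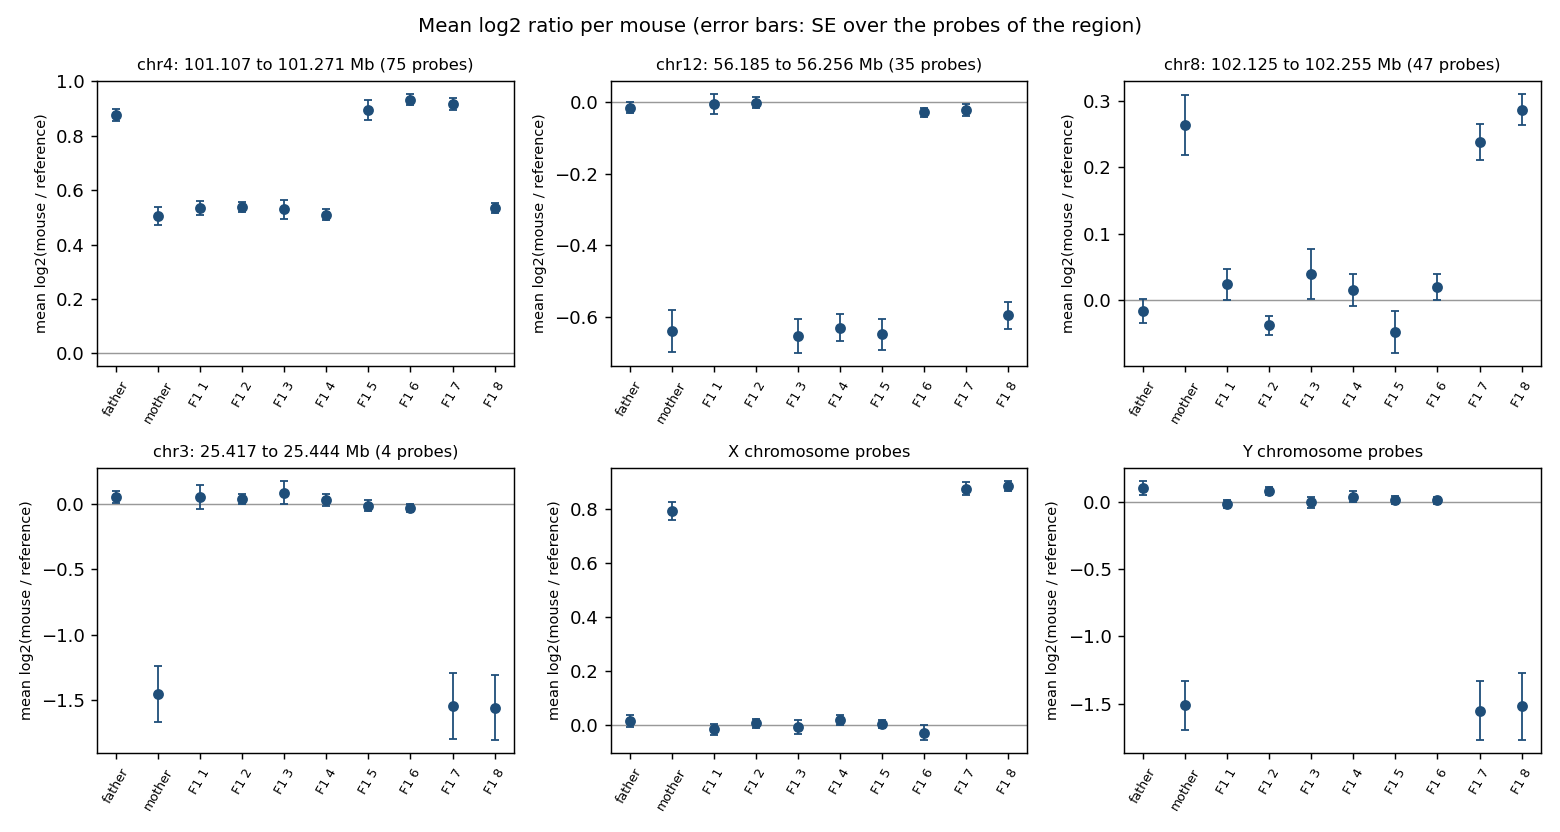
Mean log2 ratio of mouse over reference (vertical axes) for each of the 10 mice (horizontal axes) over 4 autosomal segments and over the X and Y probes; points are means over probes and bars are standard errors over probes. On chromosome 4 the mice lie near 0.5 or near 0.9, and on chromosome 12 the mother and F1 replicates 3, 4, 5 and 8 lie between -0.65 and -0.59.

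A further 3 segments were called in 2 mice. A loss on chromosome 14 (61798066 to 61822629, 14 probes) was called in F1 replicate 7 (-0.28 ± 0.06) and F1 replicate 8 (-0.27 ± 0.04) and in neither parent, although the mother had -0.24 ± 0.06. The other 7 mice lay between -0.09 and 0.06, so the low values lie in the same 3 mice as the chromosome 3 and 8 calls. It was called in 0 mice from either orientation alone or against the median of the other mice, and in 1 mouse with normexp or at a score of 8. A loss on chromosome 17 (3006536 to 3031159, 12 probes) was called in the mother (-0.66 ± 0.06) and F1 replicate 3 (-0.51 ± 0.06). The 2 orientations of F1 replicate 3 gave -0.81 and -0.21 there, and the loss was called in 0 mice from the Cy3 orientation alone or at a score of 8, in 1 with loess and in 3 with normexp. For this loss, 1 of 8 F1 carriers gave an exact two-sided binomial p = 0.0703 (adjusted p = 0.0914). The adjusted p is lowered by the regions with 0 carriers in the same adjustment, which are given below. The number of carriers depends on the processing. F1 replicate 1 had -0.27 ± 0.03 and was called with normexp, and with loess only the mother was called. The other mice without a call lay between -0.12 and 0.08. A loss on chromosome 19 (39101968 to 39110200, 3 probes) was called in F1 replicate 3 (-1.16 ± 0.54) and F1 replicate 4 (-0.62 ± 0.23), and the mother had -0.87 ± 0.31 without a call. With normexp the means of the called mice were -0.29 and -0.13. This loss was called in 0 mice with normexp, with at least 5 probes, at a score of 8, against the median of the other mice, from the Cy3 orientation alone or with only probes well above background, and in 1 from the Cy5 orientation alone.

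The scan made 85 calls in the 10 mice, 31 gains and 54 losses, which merged into 65 regions. This balance depends on the dye orientation, with 16 gains and 209 losses with the mouse in Cy5 alone and 106 gains and 16 losses with the mouse in Cy3 alone. With normexp it was 13 gains and 52 losses, and at a score of 8 it was 12 gains and 9 losses. The same scan made 109 calls on the dye background, 54 to 81 calls (mean 65.2) in 5 permutations with a probe order of its own for each mouse, and 44 to 87 in 20 permutations with 1 order for all mice. The number of calls in the mice lay below the dye background, above the range of the first kind of permutation and near the top of the range of the second. The dye background was 3 gains and 106 losses, so the 31 gains in the mice lay above it and the 54 losses below it. At a score of 8 or more there were 21 calls in the mice, 1 on the dye background and at most 3 in an order permuted for each mouse. These 21 calls were 10 on chromosome 4, 5 on chromosome 12, 3 on chromosome 3, 2 on chromosome 8 and 1 on chromosome 14, all in the segments described above. In the data 7 regions were shared by 2 or more mice. Orders permuted for each mouse gave 0, but they remove what the mice share probe by probe, such as the r of 0.52 between the mother and F1 replicate 3. With 1 order for all mice, which keeps this, 4 of 20 permutations had a shared region, with at most 2 per permutation. Of these regions, 1 was shared by the mother and F1 replicate 3, and 1 by 4 mice, the father and F1 replicates 5, 6 and 7. The others were shared by F1 replicates 6 and 7, 6 and 8, or 7 and 8. Those 4 mice are the ones with the higher chromosome 4 level, whose values the permuted orders still hold. The highest score of a shared region in these permutations was 7.54, above the 6.67 of the chromosome 19 loss and below the 7.80 of the chromosome 17 loss.

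**Figure D2:**
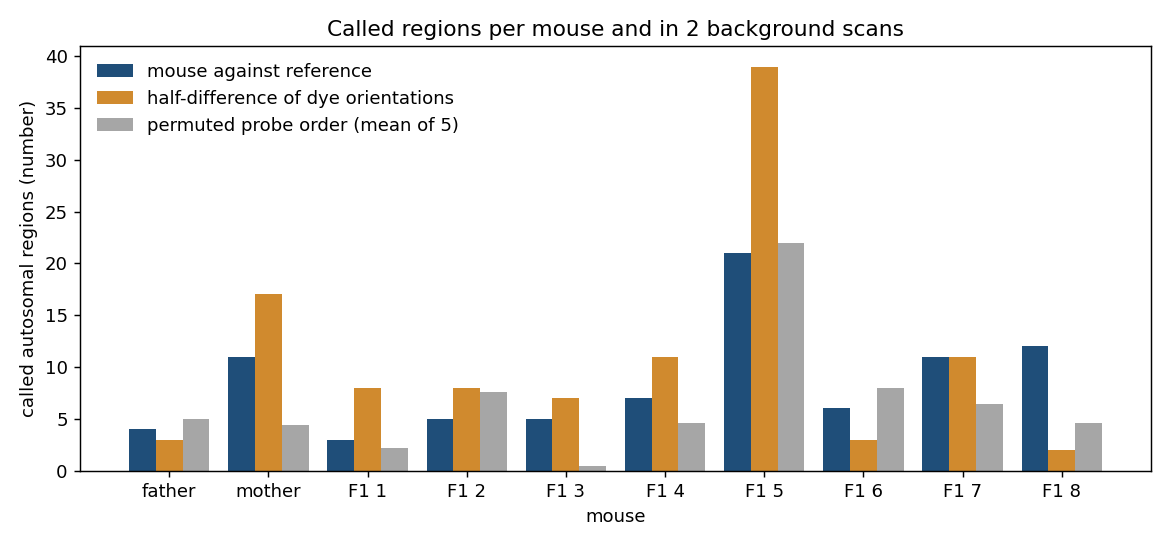
Number of called autosomal regions (vertical axis) per mouse (horizontal axis) in the data, in the scan of 0.5 of the difference between dye orientations, and as the mean of 5 scans with permuted probe order. F1 replicate 5 has 21 calls in the data, 39 on the dye background and a mean of 22.0 in permuted orders.

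The second question, the one the design was built for, is which regions appear in F1 mice and in neither parent. There were 51 such regions, 16 gains and 35 losses, and 49 of them were called in 1 mouse. The count follows the calls, so it includes regions in which a parent lay near the called level without a call. The mother was low as well in the chromosome 14 and 19 losses (-0.24 and -0.87). In a gain on chromosome 4 in F1 replicate 8 a parent had 0.49, against 0.56. In a loss on chromosome 12 outside the named regions a parent had -0.52, against -0.48 in F1 replicate 8. The looser carrier rule, which adds mice past 0.5 of the called mean, gave 41. In the mother, the scan found 2.0% of simulated losses and 0.0% of gains with 3 probes. Here too the balance depends on the orientation, with 1 gain and 160 losses with the mouse in Cy5 alone, 86 gains and 4 losses with the mouse in Cy3 alone, and 2 gains and 21 losses with normexp. At a score of 8 there were 1 gain and 1 loss. Permuted probe orders gave 48 to 69 (mean 55.8), and 38 to 77 (mean 55.2) with 1 order for all mice. Their median length was 3 probes and 6.22 kb, 37 of them had 3 or 4 probes, and their scores ran from 6.02 to 8.12. F1 replicate 5 alone held 19 of the 51. Its highest-scoring losses were on chromosome 8 (94811665 to 94817837, -1.45), chromosome 14 (51255872 to 51268790, -0.70), chromosome 5 (10417968 to 10421556, -0.99) and chromosome 3 (111007266 to 111016111, -1.15), and its highest-scoring gain was on chromosome 1 (194913228 to 194915797, 0.97). Further losses among its highest-scoring regions were on chromosome 18 (38845826 to 38854676, -0.83), chromosome 17 (72582538 to 72586949, -0.92), chromosome 7 (107325133 to 107328247, -0.87), chromosome 8 (34760155 to 34765114, -0.78) and chromosome 14 (70255013 to 70259826, -1.49). The 2 orientations differed by at least 0.46 in all 19 of its calls. Outside F1 replicate 5, the highest-scoring regions of single mice were a loss on chromosome 17 in F1 replicate 7 (33683925 to 33689650, -0.70), a gain on chromosome 14 in F1 replicate 7 (89472910 to 89478182, 0.64), a loss on chromosome 2 in F1 replicate 8 (70079530 to 70084238, -0.64) and a loss on chromosome 12 in F1 replicate 6 (88471378 to 88479312, -0.42), of 3 to 5 probes each. They were followed by a gain on chromosome 7 (47257189 to 47265494, 0.58), a gain on chromosome 4 (21366134 to 21372719, 0.56) and a loss on chromosome 3 (59835645 to 59838500, -0.50), all in F1 replicate 8, and a gain on chromosome 3 in F1 replicate 6 (71991762 to 72005226, 0.45). Each region named here for a single mouse had a score below 8. With the calls of F1 replicate 5 left out, 32 regions remained in F1 mice and neither parent, and at a score of 8 there were 2, the chromosome 8 and chromosome 14 segments, in which the mother had 0.26 and -0.24.

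Regions called in 1 parent and in 0 of 8 F1 mice numbered 3 for the father and 6 for the mother. The father's were a loss on chromosome 12 (37138302 to 37147590, 3 probes, -0.60), a gain on chromosome 2 (84660905 to 84679268, 10 probes, 0.35) and a gain on chromosome 6 (123842634 to 123862023, 4 probes, 0.76). The highest-scoring of the mother's was a loss on chromosome 14 (52008939 to 52020523, 4 probes, -1.04). Their scores lay between 6.03 and 7.11, in the range that the permuted orders also reached. For each of the 9, the exact two-sided binomial p was 0.00781 (adjusted p = 0.0113), which follows from 0 carriers, by which these regions are grouped, and is no evidence of a departure from 0.5. Because the 9 enter the same adjustment, they also lower the adjusted p of the regions with carriers given above.

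Probe by probe, the screen for a log2 ratio of at least 0.5 in both orientations gave 47513 calls over the 10 mice, 20517 gains and 26996 losses, against 78248 with opposite directions. The mother gave 25007 and F1 replicate 3 gave 12915, and the other 8 mice gave 626 to 1909 each. Without these 2 mice the total was 9591. In the mother and F1 replicate 3 the calls outnumbered the opposite-direction probes (9534 and 4686), and in each of the other 8 mice they did not. One probe outside the chromosome 4 segment passed the screen in all 10 mice, A_67_P07959016 on chromosome 13 (95707465 to 95707524), with 1.54 ± 0.40 (SD, n = 8) in the F1 mice, 2.00 in the father and 1.67 in the mother. The medians of its neighbours over the mice were 0.03 and -0.03.

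As a group, the 8 F1 mice differed from the reference at 63 of 950621 probes (limma, Benjamini-Hochberg adjusted p under 0.05), 58 higher and 5 lower, all with a mean of at least 0.25 in size. The chromosome 4 segment held 53 of them. Of the other 10, 5 were higher and 5 lower, led by A_67_P07959016 (adjusted p = 0.0010) and A_67_P07457079 on chromosome 11 (97822604 to 97822658, -0.56, adjusted p = 0.0043). With scan batch as a random block, where the estimated correlation within a batch was -0.023, the count was 63. Within batch 2 (F1 replicates 1 and 2) it was 12, within batch 3 (replicates 3 and 4) it was 747 and within batch 4 (replicates 5 and 7) it was 0, with 2 mice each. With F1 replicates 1, 3 and 4 left out, it was 1, while the sizes stayed. The median size over the 53 chromosome 4 probes was 0.75 with 8 mice and 0.82 with 5 (median SE 0.07 and 0.08), and over the other 10 probes 0.37 and 0.36 (median SE 0.05 and 0.06). All 63 kept their sign and an unadjusted p under 0.05 (limma). They were chosen in a fit that held the same 5 mice, so this was nearly fixed in advance. Over all probes, the number at an unadjusted p under 0.05 (limma) went from 132926 to 54450. No other 3 mice were left out together. The effect of fewer mice and that of the correlated values of F1 replicates 1, 3 and 4 therefore cannot be told apart.

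The F1 mice and the parents differed at 0 of 950617 probes (limma), with 79660 at an unadjusted p under 0.05 and a smallest adjusted p of 0.258. Both parents lie in 1 scan batch of their own, so a batch difference and a difference between F1 mice and parents cannot be told apart. With batch as a random block the count was also 0, which does not separate them. The estimated correlation within a batch was -0.15 there. Leaving out the father gave 13012 probes and leaving out the mother gave 119, where the lone parent is assumed to vary like the F1 mice.

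The chromosome means of the 10 mice lay between -0.015 and 0.0072, and of the 19 autosomes 0 passed the exact sign-flip permutation test after adjustment (smallest adjusted p = 0.992), with 0 at an unadjusted p under 0.05. The smallest unadjusted p was 0.0547, on chromosome 2, where the F1 mean was -0.0022 and 7 of 8 F1 mice lay on the same side of 0. The smallest p that 8 mice allow is 0.00781, which adjusts to 0.148 for 1 autosome of 19. At least 3 autosomes would have to reach it together, so this test could not pass a single autosome. With medians over probes in place of means, 2 autosomes had an unadjusted p under 0.05, the smallest at 0.00781, and 0 passed after adjustment (exact permutation test, smallest adjusted p = 0.148).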

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

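The tests on F1 replicate 5, on scan batch, on the size of the intensity trend and on the chromosome 3 and chromosome 8 segments were chosen after the results were seen, and the one between different spots was set before its value was seen. The tests of a lost copy on chromosome 3 and a gained copy on chromosome 8 first used the chromosome 12 level, whose copy number is not known, and counted against both. They were replaced after those values were seen, and the one on Y was then also run with normexp. Of 56 F1 values tested, 26 had 1 mouse far from the other 7. Chance gives this in about 1 in 20 groups, and a region called in 1 mouse stands apart because it was chosen for that.

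F1 replicate 3 stood apart in the correlation of its orientations (r = 0.161, others -0.44 to -0.171) and in the single-probe screen (12915, others 626 to 1909). F1 replicate 5 stood apart in the calls on the dye background (39, others 2 to 11). It had the lowest chromosome mean of the F1 mice on all 19 autosomes, and it lay far from the other 7 on chromosomes 1 (-0.0104), 2 (-0.00975), 3 (-0.0121), 6 (-0.0115), 8 (-0.0111), 9 (-0.0097), 12 (-0.0105), 13 (-0.0124) and 14 (-0.0126). In regions called in F1 replicate 5 alone its values were -1.45 and -0.78 on chromosome 8, 0.97 on chromosome 1, -0.70 and -1.49 on chromosome 14, -0.99 on chromosome 5, -1.15 on chromosome 3, -0.83 on chromosome 18, -0.92 on chromosome 17 and -0.87 on chromosome 7. The others were -0.70 on chromosome 17 in F1 replicate 7, -0.42 on chromosome 12 and 0.45 on chromosome 3 in F1 replicate 6, and -0.50 on chromosome 3 in F1 replicate 8.

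The 19 regions called in F1 replicate 5 and no other mouse argue against copy number differences of that mouse, because their orientations differ by a median of 1.23 on the log2 scale, against at most 0.132 in its chromosome 4 and 12 calls. Bright patches may have made the 16 that are larger in the array with the mouse in Cy5, while the 3 gains on chromosomes 1, 13 and 14 are larger in the other array. In the Cy5 array the probes of all 19 lie a median of 57.3 position units from the nearest outlying spot, against 111 for the chromosome 4 and 12 probes, a ratio of 0.518 ± 0.208 (SE), and in the Cy3 array 88.8 against 136. The bound set was 0.5, and the Cy5 ratio lies within its error of it, so patches stay open. The verdict first took the bound without the error and counted against patches, and the error was added after that value was seen.

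Probe values went together in the mother and F1 replicates 1, 3 and 4. Across probes, which are not independent replicates, the mother and F1 replicate 3 correlated with r = 0.521 between different spots of the same probes, which argues against a shared place on the array. The trends that loess removed held 0.109% of the variance in the mother and 0.129% in F1 replicate 3 and gave 0.000284 of their r of 0.52, which argues against an intensity trend of the kind that loess finds. The highest r between mice of different scan batches was 0.611, against 0.358 within a batch, but few pairs lie within a batch. The mother, F1 replicate 1 and F1 replicate 3 lie in different scan batches and correlated with r from 0.461 to 0.611. This argues against a shared scan batch for these mice. Other batches, as of labelling or hybridisation, were not tested. No biological explanation was tested.

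The loss on chromosome 3 and the gain on chromosome 8 were called in the mother and F1 replicates 7 and 8. The chromosome 3 level lies at least 2.11 standard errors below the unscaled level of 1 copy against 2, short of the 3.18 that 4 probes ask for, so the loss of 1 autosomal copy stays open. It lies within 0.203 standard errors of the same mouse's Y mean, but 3.55 to 4.42 from it with normexp. The Y mean is the level of sequence that lies on Y alone. Sequence on both chromosome 3 and Y would give a level set by its number of copies on Y, which is not known. The comparison therefore does not test sequence shared with Y, which stays open. The chromosome 8 level lies at least 4.02 standard errors below 3 copies against 2 scaled by the X mean of the same mouse. Over each mouse's own call the distance is at least 3.21. On the processed signals this argues against 1 inherited extra copy in these 3 mice, if the X mean is a fair scale for the segment. With normexp the distance came as near as 0.678. Normexp shrank the sex chromosome means more than these segments. In F1 replicate 7, X went from 0.87 to 0.53 and Y from -1.55 to -0.58. Its chromosome 8 mean went from 0.24 to 0.23 and its chromosome 3 mean from -1.54 to -1.51. Distances on the X or Y scale with normexp therefore cannot decide either question. Sequence shared with X stays open and untested by the choice of mice, which prompted it: a level of 4 copies against 3 on the X scale lies up to 4.30 standard errors away, sharing over part of the segment would give other levels, and no probe sequence was compared with X or Y.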

How the results depend on the processing

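Runs that left out mice or calls by name, the score of 8 for regions by family member, and the alternatives for regions in 2 or more mice and for sex chromosome and region means were chosen after the results were seen. Of the main counts and values, 46 alternatives stayed close and 23 moved. Those that stayed include counts of 0 against 0, for F1 against parents and for the chromosome means, which say little about stability. Of the means of shared regions, 65 stayed, 16 moved and 0 changed sign. The 85 called regions became 597 at a score of 5, 21 at a score of 8, 174 with at least 2 probes, 52 with at least 5 probes, 225 from the Cy5 orientation alone, 122 from the Cy3 orientation alone, 52 with only probes well above background and 48 without the mother and F1 replicates 3 and 5. The screen total of 47513 became 169058 at 0.35, 6568 at 0.75, 13311 with normexp and 9591 without the mother and F1 replicate 3. Regions in F1 mice and neither parent went from 51 to 32 without the calls of F1 replicate 5 and to 2 at a score of 8. Regions in 2 or more mice went from 7 to 28 under the looser carrier rule and to 4 at a score of 8. F1 against the reference gave 63 probes, and 12 within scan batch 2, 747 within batch 3, 0 within batch 4 and 1 without F1 replicates 1, 3 and 4; leaving out 1 F1 mouse gave 45 to 58. F1 against parents gave 0 probes, and 0 to 13012 when 1 mouse was left out (13012 without the father, 119 without the mother). With normexp the mother's X mean was 0.453 and the Y mean -0.547. The cause was not tested where a value moved, except that stricter or looser thresholds change counts by construction. Calls summed over mice also fall by construction when mice are left out. The limma counts went both ways with fewer mice, and the cause of that was not tested.

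The gene lists and the GC trend were planned and not run. Of the 950622 autosomal probes, 916006 were well above background on all arrays. With only these, the screen total of 47513 became 35972, which counts as close.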

Other observations

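All tests in this part were chosen or given their criterion after the results were seen, although the count of other splits was planned. Both chromosome 4 explanations were first held to be met on the processed signals alone, and the runs with normexp were added after that. On chromosome 4 every F1 mouse lay within 1.80 standard errors of the nearer parent's level and at least 7.91 from the other's, with 3 nearer the father and 5 nearer the mother. These errors treat the probe values of F1 mouse and parent as independent. The probes are the same in both, and this pairing was not used, so paired distances may differ. With normexp the nearer parent was the same in all 8, but a mouse lay up to 4.31 standard errors from it, and at least 6.50 from the other. Levels passed on from the parents stay open, since the 2 signal settings differ on whether the F1 mice match the mother's level.

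For chromosome 4, 3 and 4 copies against 2 in the reference stay open. The mother and F1 replicates 7 and 8 lay within 1.33 standard errors of those levels scaled by their own X means, and at least 5.98 from 2 and 3 copies against 1. With normexp, where the mother's X mean was 0.453 and the chromosome 4 mean 0.346, a mouse lay up to 6.47 from the first and as near as 0.0951 to the second. In F1 replicate 7 normexp took the X mean from 0.87 to 0.53 and the chromosome 4 mean from 0.92 to 0.83. The X mean may therefore be no scale for this segment with normexp, and those distances do not decide. The ratio of the mother's mean to the father's needs no scale only if the processing shrinks both alike. It was 0.576 ± 0.0331 (bootstrap SE over probes), against 0.585 for 3 and 4 over 2, 0.631 for 2 and 3 over 1 and 0.563 for 4 and 5 over 3, and does not separate them. With normexp the mother's mean went from 0.505 to 0.346 and the father's from 0.877 to 0.776, so the ratio depends on the signal setting. Without scaling, 4 and 5 copies against 3 lay 2.68 standard errors below the mother's level and 6.26 below the father's on the processed signals.

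For F1 against parents the real split gave 0 probes, so all 45 splits of the 10 mice into 8 and 2 gave at least as many by construction, and the count says nothing about chance. The highest other split, the mother and F1 replicate 3 against the rest, gave 49635. These mice had the largest derivative spreads, 0.29 and 0.25. F1 replicates 1 and 3 against the rest, the pair with the highest r of 0.611, gave 0. The cause of the high split was not tested.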
